A study of Mus musculus with 8 samples.

How the data were processed

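Small RNA libraries were made from total RNA of flow-sorted bone marrow LSK cells of 4 db/m and 4 db/db samples, the RNA having been isolated with Trizol, per the labels' protocols. The libraries used the QIAseq miRNA kit with 50 ng of RNA each and shared 1 NextSeq run, with 134 M reads passing filter, 40% PhiX and 92% of bases at Q30, per the run table and notes of the deposited project sheet, whose heading names a MiSeq Dx instead. As all 8 libraries shared that run, no sequencing batch could be set against the genotypes. The titles open with a 6-digit number that 1 to 3 libraries of a genotype share, and no number occurs in both genotypes. In the column names a letter code follows it, and each library has its own pairing of number and code. What they stand for is not stated in the sources used here.

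The authors deposited whole-number counts per mature miRNA for each library, called raw counts and listed by miRBase name per the file headers. The same table holds log2 CPM values per library that the authors computed, per the file headers, and the authors' log2 fold change, signed fold change (read here as a score), p-value and false discovery rate of diabetic against control libraries. The deposited project sheet gives an RNA integrity number per RNA sample, read here as a score, per the file headers. edgeR 3.41.9 and the mm10 build are named per the submitters' processing notes. The aligner, the treatment of molecular identifiers and any filter on low counts before deposit are not given in the sources used here, so a count can be a read or a molecule, and intervals drawn from counts cover counting error only. The table holds 190 miRNAs and no other small RNA class. The way reads that match several near-identical miRNAs were assigned is not given in the sources used here, so members of families such as let-7, miR-181, miR-101 and miR-466 are uncertain. 0 columns of values per library were left without a sample.

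The authors' log2 fold changes and p-values were matched by edgeR's likelihood ratio test on all 190 miRNAs with TMM scaling. The largest difference was 1e-14 in log2 fold change, 9.5e-09 in p and 5e-14 in log2 CPM, within a tolerance of 1e-06. This recomputation used the group assignment taken from the genotype and strain labels, since the titles and the project sheet call all 8 samples db/m. Columns were joined to samples through the number and suffix in their names.

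Counts were tested with edgeR 4.0.16 in R 4.3.3. miRNAs were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 144. Library sizes were scaled by TMM, dispersions estimated with estimateDisp, and genotypes compared with glmQLFit (robust) and glmQLFTest at 6 residual degrees of freedom. p-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. The SE of a log2 fold change was taken as its size over the square root of the F statistic. CPM values are counts over the TMM-scaled library size, given as mean ± SD. The biological coefficient of variation was 0.275, and the SE of the log2 fold changes had a median of 0.32 and ran from 0.11 to 0.86. On simulated data with the means, dispersions and library sizes of these libraries (40 tables of 144 miRNAs for the comparison of db/db with db/m, 24 changed in each), 56.5% of miRNAs changed 2-fold and 92.1% of those changed 4-fold passed, and 5.56% of calls were false. In tables simulated in the same way, the stem and progenitor list of 14 tested miRNAs, shifted by a log2 fold change of 0.5, was called in 100%. Without a shift 0.075 lists were called per table. The miRNAs were drawn independently of each other, so these rates do not cover correlated miRNAs, and the 100% does not extend to the smaller lists. Nor does it cover a smaller or uneven shift. The stem and progenitor list as observed had a median of 0.28, with members from -1.42 to 1.60.

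The 17 lists of miRNAs covered stem and progenitor cells, the miR-17 clusters, the let-7, miR-29, miR-30 and miR-15/16 families, erythroid, myeloid and lymphoid cells, stromal and endothelial cells, other tissues, the Dlk1-Dio3 and Sfmbt2 clusters, NF-kB and inflammation, diabetes and high glucose, hypoxia and p53, and the neighbour of Lepr. The 11 with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided. camera was also run with a correlation estimated per list, and fry was run on the same values. Totals, numbers of miRNAs with a count and shares of the most abundant miRNAs were compared by an exact two-sided permutation test over the 70 assignments of the 8 libraries. The let-7 share and the RNA integrity number were added to that family after the data were examined.

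The miRNAs named in the text follow a rule fixed before the data were examined. It takes those past the threshold with at least 10 CPM on average, up to 12 per direction. Where fewer than 5 pass in a direction it adds the 5 with the smallest p there, which was read after the values were seen as 5 that did not pass. It adds the 10 most abundant miRNAs, the member of each list with the smallest p and the most abundant one, and 11 miRNAs chosen from knowledge of blood and diabetes. Any others were chosen after their values were seen.

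Each library counted as 1 replicate. Pairs of libraries within a genotype differed by more than counting noise (chi-square per degree of freedom from 5.76 to 14.3), so no column copies another, which does not tell separate animals from repeat preparations. Hairpin positions, host genes and GC content came from GENCODE vM21 on GRCm38, which is the mm10 assembly, with 189 of 190 names matched to a hairpin gene.

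The alternatives tried were RLE size factors, library totals without scaling factors, library size without the 5 most abundant miRNAs, no filter, a filter at 10 CPM in 4 libraries, DESeq2 1.42.0, the likelihood ratio test, limma-voom with and without the title number as a random block, sums over libraries that share a title number, the number after the hyphen of the title as a block, an adjusted p of 0.1, and each library left out in turn. The authors' test as recovered from the table was added after the data were examined. Restricting the test to mature miRNAs was not run because the table holds nothing else.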

Results

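MicroRNAs (miRNAs), short RNAs that lower the output of matching messenger RNAs, were counted by small RNA sequencing in mouse bone marrow LSK cells. LSK cells are sorted as lacking lineage markers and carrying Sca1 and cKit, a fraction that holds haematopoietic stem cells and multipotent progenitors. The design compared db/db mice, homozygous for the db mutation of the leptin receptor gene Lepr and a model of obesity with type 2 diabetes, with heterozygous db/m mice. It asks which LSK miRNAs differ in level between the genotypes. The labels put all samples at 6 months of diabetes. Each genotype had 4 libraries. The title of every library reads db/m, so the groups follow the genotype and strain labels, which split the 8 libraries evenly. The authors' own comparison of diabetic with control libraries, recomputed with this split, had the same sign and size for all 190 miRNAs. The columns of each library carry their own pairing of a number and a letter code, but nothing in the labels says what these mark or whether the libraries came from separate animals, so p-values here measure only the spread between these samples.

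The table held 190 mature miRNAs and 371637 counts over the 8 libraries. Total counts were 40539, 13273, 77834 and 54642 in db/m replicates 1 to 4, and 54228, 50128, 36145 and 44848 in db/db replicates 1 to 4. The mean totals, 46570 ± 27000 in db/m and 46340 ± 7805 in db/db (SD, n = 4 each), did not differ past the threshold (exact two-sided permutation p = 0.943). At these depths 3 counts are worth between 40.3 CPM (counts scaled to a common library size) in db/m replicate 3 and 229 CPM in db/m replicate 2, so low miRNAs were measured coarsely. A minimum count left 144 miRNAs for testing, with 99.3% of all counts. The number of miRNAs with a count was 187.5 ± 5 in db/m and 189.8 ± 0.5 in db/db (SD, n = 4 each; exact permutation p = 1). RNA integrity numbers were 9.88 ± 0.25 in db/m and 9.95 ± 0.10 in db/db (SD, n = 4 each; exact permutation p = 1).

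Let-7 miRNAs, which accumulate in differentiated cells, took a large share of the miRNA counts in both genotypes. The 9 let-7 members held 41.6% ± 1.01 of the counts in db/m and 37.9% ± 1.98 in db/db (SD, n = 4 each; exact two-sided permutation p = 0.0286). The 5 most abundant miRNAs, let-7a-5p, let-7c-5p, let-7b-5p, miR-16-5p and let-7f-5p, took 45.1% ± 0.617 in db/m and 41.2% ± 1.15 in db/db (SD, n = 4 each; exact permutation p = 0.0286). That p is the smallest that 4 libraries against 4 can give, and after Benjamini-Hochberg adjustment over the 5 library measures compared it became 0.0714 for both shares, so neither passed 0.05, which a pair of measures at that smallest p cannot do in a family of 5. Without any of the 4 db/m libraries in turn, the exact permutation p of the let-7 share was 0.0571. By mean CPM the 10 most abundant miRNAs were these 5, at 97440, 96350, 91460, 83720 and 67040, followed by miR-92a-3p at 61930, miR-191-5p at 32200, miR-125a-5p at 31720, miR-26a-5p at 26610 and miR-125b-5p at 24650. No member of this group of 10 passed adjusted p of 0.05 between the genotypes. Mature let-7 sequences are nearly identical, so counts of single members can have been split or exchanged between them.

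Among the 144 tested miRNAs the largest log2 fold change was that of miR-126a-5p, and both strands of its hairpin rose in db/db LSK cells. miR-126 is known to restrain cell-cycle entry of haematopoietic stem cells and to be abundant in endothelium. miR-126a-3p rose 2.61-fold, from 9312 ± 1727 to 24200 ± 7669 CPM, and miR-126a-5p rose 3.03-fold, from 2076 ± 556 to 6171 ± 2022 CPM (SD, n = 4 each). miR-30a-5p rose 2.55-fold, from 300.9 ± 60.5 to 801 ± 285 CPM, and miR-196b-5p, encoded in the Hoxa gene cluster, rose 1.68-fold, from 5369 ± 868 to 9018 ± 1506 CPM. The miR-30a-5p values rest on few counts, 3 to 28 per db/m library and 24 to 63 per db/db library. miR-148a-3p fell 2.64-fold, from 19820 ± 5297 to 7496 ± 3471 CPM, miR-423-5p fell 2.63-fold, from 8114 ± 1812 to 3088 ± 859 CPM, and miR-320-3p fell 2.04-fold, from 2154 ± 341 to 1066 ± 142 CPM. For each of these 7 miRNAs the 4 db/db libraries lay on 1 side of the 4 db/m libraries.

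By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7 of 144 miRNAs passed adjusted p of 0.05, 4 higher and 3 lower in db/db. At unadjusted p under 0.05 there were 32, 15 higher and 17 lower, where chance alone gives 7.2. The log2 fold changes were 1.60 (SE 0.28, adjusted p = 0.00532) for miR-126a-5p, 1.38 (SE 0.25, adjusted p = 0.00532) for miR-126a-3p, 1.35 (SE 0.34, adjusted p = 0.0358) for miR-30a-5p and 0.75 (SE 0.19, adjusted p = 0.0436) for miR-196b-5p. They were -1.39 (SE 0.25, adjusted p = 0.00532) for miR-423-5p, -1.03 (SE 0.23, adjusted p = 0.0198) for miR-320-3p and -1.40 (SE 0.33, adjusted p = 0.0299) for miR-148a-3p. The groups did not overlap for 25 tested miRNAs, 12 higher and 13 lower, where chance gives 2.86% of them or 4.11. The calls of miR-126a-3p, miR-126a-5p and miR-423-5p held without any library in turn. The other 4 lost theirs without some single libraries, while their log2 fold changes stayed between -1.15 and -0.97 for miR-320-3p, -1.64 and -1.24 for miR-148a-3p, 1.05 and 1.45 for miR-30a-5p, and 0.60 and 0.86 for miR-196b-5p. Without db/m replicate 1, db/m replicate 4 or db/db replicate 1 the count fell to 3, and without db/m replicate 3 it was 16. Adjusted p without those first 3 libraries was 0.0726, 0.0702 and 0.0533 for miR-320-3p, 0.0924, 0.0611 and 0.101 for miR-148a-3p, 0.0924, 0.101 and 0.107 for miR-30a-5p, and 0.0641, 0.167 and 0.112 for miR-196b-5p. Without db/db replicate 2 it was 0.113 for miR-30a-5p and 0.119 for miR-196b-5p, and without db/m replicate 2 it was 0.0634 for miR-196b-5p. With libraries of 1 title number summed, the log2 fold change of miR-148a-3p was -1.13 at an adjusted p of 0.442, and without a filter miR-30a-5p (1.28, adjusted p = 0.0578) and miR-196b-5p (0.67, adjusted p = 0.0864) did not pass.

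**Figure D1:**
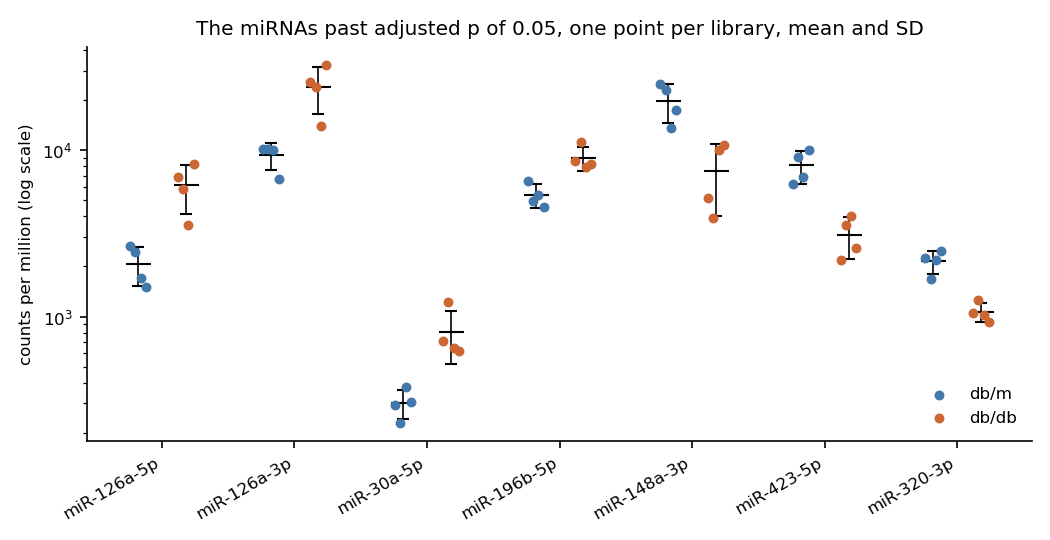
CPM (log axis) of the 7 miRNAs past adjusted p of 0.05, with 1 point per library, 4 db/m and 4 db/db libraries for each miRNA, and the mean with SD as black bars. In each miRNA the libraries of the genotypes do not overlap, as for miR-126a-3p with 6724 to 10240 CPM in db/m and 14100 to 32680 CPM in db/db.

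In GRCm38 coordinates (mm10), the miR-126a hairpin lies on chromosome 2 from 26591357 to 26591429, on the strand of Egfl7 and within an annotated exon of that gene. The miR-196b hairpin lies on chromosome 6 from 52230081 to 52230165, in an exon of the Hoxa9 annotation on the same strand, and the miR-148a hairpin on the same chromosome from 51269812 to 51269910, outside annotated genes. The miR-423 hairpin lies in an intron of Nsrp1 on chromosome 11 from 77078064 to 77078172. The hairpins of miR-320 (chromosome 14, 70443510 to 70443591) and miR-30a (chromosome 1, 23272269 to 23272339) lie in no annotated host gene.

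The next miRNAs by p did not pass the threshold. On the higher side, log2 fold changes were 1.00 (SE 0.32, adjusted p = 0.091) for miR-181c-5p, 1.08 (SE 0.35, adjusted p = 0.0916) for miR-101a-3p, 0.57 (SE 0.19, adjusted p = 0.107) for miR-29a-3p, 0.87 (SE 0.29, adjusted p = 0.107) for miR-29c-3p and 0.46 (SE 0.16, adjusted p = 0.111) for miR-26a-5p by edgeR. On the lower side they were -0.96 (SE 0.26, adjusted p = 0.0549) for miR-25-5p, -1.17 (SE 0.33, adjusted p = 0.0563) for miR-1981-5p, -0.38 (SE 0.11, adjusted p = 0.0637) for let-7a-5p, -0.82 (SE 0.24, adjusted p = 0.0637) for miR-128-3p and -1.42 (SE 0.49, adjusted p = 0.111) for miR-22-3p. In each of these 10 all 4 db/db libraries also lay on 1 side of the 4 db/m libraries. Single libraries moved some of them past the threshold. Without db/m replicate 3, edgeR adjusted p was 0.0328 for miR-101a-3p, miR-25-5p and let-7a-5p, and without db/m replicate 2 it was 0.0355 for miR-25-5p. It was 0.0387 for miR-1981-5p and let-7a-5p without db/db replicate 3, 0.0202 for let-7a-5p without db/db replicate 2, and 0.026 for miR-128-3p and 0.0128 for miR-22-3p without db/db replicate 4.

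**Figure D2:**
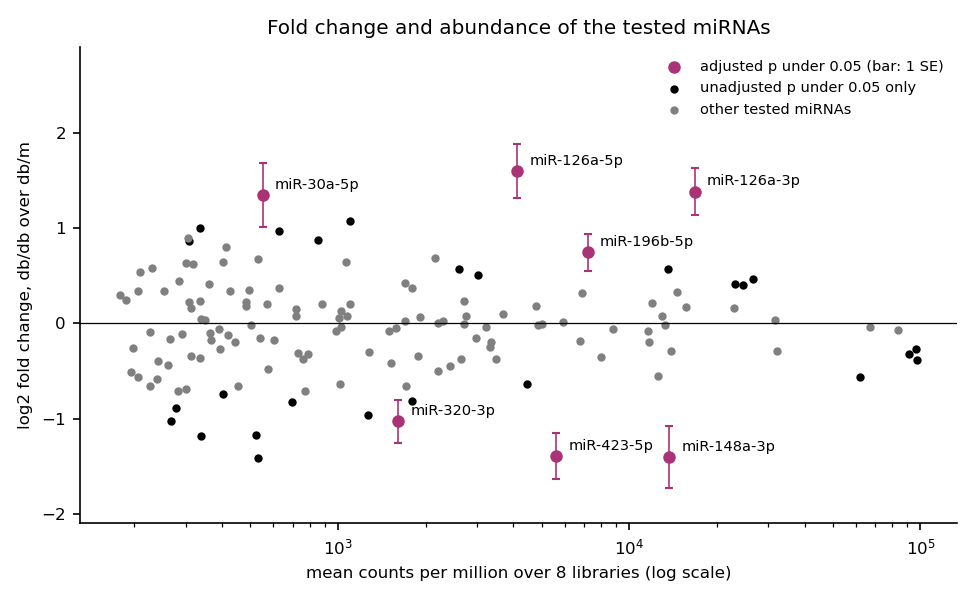
log2 fold change of db/db over db/m against mean CPM over the 8 libraries (log axis) for the 144 tested miRNAs. The 7 past adjusted p of 0.05 are named and carry bars of 1 SE, black points are past unadjusted p of 0.05 only, and grey points are the other tested miRNAs. The 4 named miRNAs above 0 have log2 fold changes from 0.75 to 1.60 and the 3 below 0 from -1.40 to -1.03.

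The authors' deposited table listed 10 miRNAs at a false discovery rate under 0.05, 4 higher and 6 lower in db/db, and these included all 7 named above. The other 3 in the authors' deposited table were miR-1981-5p, with a log2 fold change of -1.25 and a false discovery rate of 0.0135, miR-25-5p (-1.06, 0.0181) and miR-128-3p (-0.90, 0.0197). For miR-126a-3p the authors' deposited table gave a log2 fold change of 1.31 and a false discovery rate of 9.1e-05. Across the 144 tested miRNAs the log2 fold changes computed here and those of the authors' deposited table had a Pearson correlation of 0.998, taken across miRNAs that are not independent replicates, and the former were higher by a median of 0.08.

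Among the 17 miRNA lists fixed beforehand, that of miRNAs known from haematopoietic stem and progenitor cells had the smallest camera p without passing adjustment, with a median log2 fold change of 0.28. Of the list's 21 members 14 were tested, 11 with a log2 fold change above 0 and 3 below. Over all tested 3 passed, all of them higher, namely miR-126a-3p, miR-126a-5p and miR-196b-5p. Adjusted over the list alone, 5 passed, the same 3 with miR-29a-3p on the higher side and miR-22-3p on the lower side. miR-125a-5p, the most abundant member and a miRNA that enlarges the stem cell pool when raised, had a log2 fold change of 0.03 (SE 0.18, adjusted p = 0.954), and miR-125b-5p 0.40 (SE 0.17, adjusted p = 0.171) by edgeR. limma's camera test of the list against the other miRNAs gave p = 0.00713 and adjusted p = 0.0784, and an estimated correlation gave p = 0.256 and adjusted p = 0.705. The list passed by camera when db/m replicate 1 (adjusted p = 0.0204), db/m replicate 2 (0.0175) or db/db replicate 3 (0.0163) was left out. Counts across lists were 0 of 11 testable lists past adjusted p of 0.05 by camera and 2 at unadjusted p under 0.05. With estimated correlations 0 passed, and by limma's fry, which asks whether members move on balance in 1 direction, 1 passed, with 3 at unadjusted p under 0.05.

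The list that passed by limma's fry was the miR-30 family (adjusted p = 0.0218). camera of limma gave it an adjusted p of 0.205, and 0.632 with an estimated correlation. Of its 6 tested members 5 had log2 fold changes above 0 and 1 below, with a median of 0.21. Only miR-30a-5p passed, over all tested and adjusted over the list alone. The most abundant member, miR-30d-5p at 12570 ± 2260 CPM in db/m and 13320 ± 1736 CPM in db/db (SD, n = 4 each), had a log2 fold change of 0.08 (SE 0.18, adjusted p = 0.925), whose sign turned when no miRNAs were filtered (-0.012). All 3 tested miR-29 members, miRNAs that target collagens and DNA methyltransferases, had log2 fold changes above 0, with a median of 0.57. None passed over all tested, and adjusted over the list alone 2 did, miR-29a-3p and miR-29c-3p. camera gave p = 0.0388 and adjusted p = 0.205 for this family, and adjusted p = 0.632 with an estimated correlation. In the let-7 family 8 of 9 tested members had log2 fold changes below 0, with a median of -0.27, or -0.17 under scaling by library totals. Of these 8, let-7e-5p lay near 0 (-0.007, SE 0.22). Over all tested 0 passed, and adjusted over the list alone let-7a-5p did (camera adjusted p = 0.205, fry adjusted p = 0.0938). let-7c-5p had a log2 fold change of -0.27 (SE 0.11), let-7b-5p of -0.32 (SE 0.13) and let-7f-5p of -0.03 (SE 0.15), the last turning to 0.07 under scaling by library totals and to 0.05 without the 5 most abundant miRNAs in the library size.

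**Figure D3:**
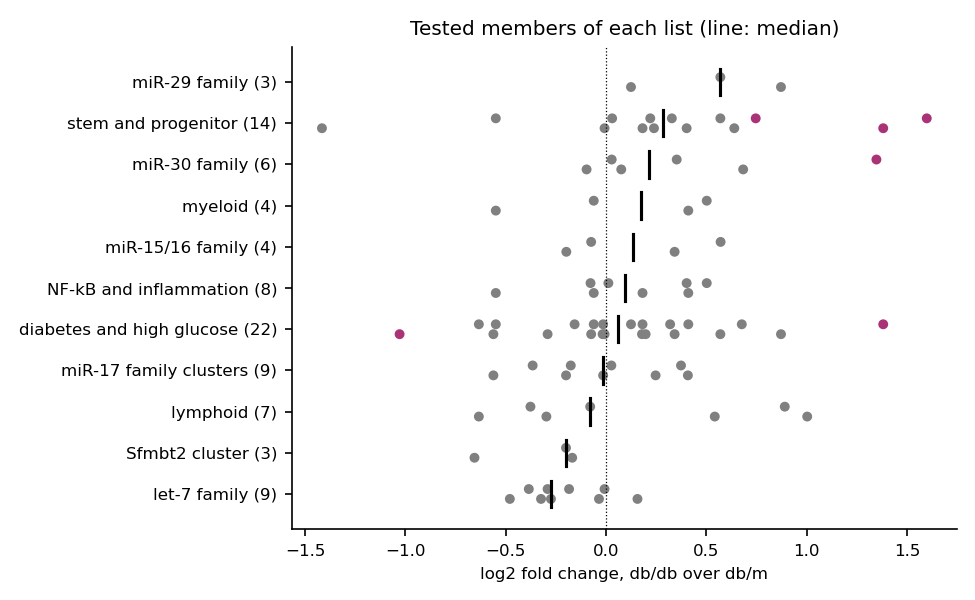
log2 fold change of db/db over db/m of the tested members of the 11 lists with at least 3 of them, the number tested in brackets. Each point is 1 miRNA, purple where it passed adjusted p of 0.05 and grey otherwise, and the black line is the median of the list, from -0.27 for the let-7 family to 0.57 for the miR-29 family.

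The miR-17 family clusters, which drive proliferation of blood progenitors, had 9 tested members with a median log2 fold change of -0.01, a mean of -0.03 and an upward camera direction (adjusted p = 0.808). That direction turned downward without db/m replicate 1 (median -0.026) or db/m replicate 2 (-0.17), and the median turned positive under RLE size factors (0.0066), library totals (0.09) and without db/m replicate 3 (0.16). Over all tested and adjusted over the list alone 0 passed, and miR-92a-3p had the smallest p (log2 fold change -0.56, SE 0.21, adjusted p = 0.136 by edgeR, and 0.0387 without db/db replicate 3). The miR-15/16 family had a median of 0.13 over 4 tested members (camera adjusted p = 0.573) and 0 passed, over all tested or adjusted over the list alone. Its most abundant member miR-16-5p had a log2 fold change of -0.07 (SE 0.12), which turned positive under scaling by library totals (0.03) or without the 5 most abundant miRNAs in the library size, miR-15a-5p 0.34 (SE 0.40) and miR-322-5p 0.57 (SE 0.25, adjusted p = 0.183). Of 3 tested members of the multicopy Sfmbt2 cluster, whose near-identical copies make counts uncertain, 0 passed, over all tested or adjusted over the list alone. Their median was -0.20 (camera adjusted p = 0.541), with -0.66 (SE 0.37) for miR-669c-5p.

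Of 22 tested miRNAs linked to diabetes or high glucose, 11 had log2 fold changes above 0 and 11 below, and the median was 0.06 (camera adjusted p = 0.541, and 0.748 with an estimated correlation). That median turned negative without db/m replicate 2 (-0.027), db/m replicate 4 (-0.0088) or db/db replicate 2 (-0.017). miR-126a-3p rose and miR-320-3p fell, and the same 2 passed adjusted over the list alone. Of 8 tested miRNAs of NF-kB and inflammatory signalling 0 passed, over all tested or adjusted over the list alone (median 0.10, and -0.048 without db/db replicate 1; camera adjusted p = 0.541). Log2 fold changes were 0.41 (SE 0.17, adjusted p = 0.171) for miR-21a-5p, 0.18 (SE 0.19, adjusted p = 0.632) for miR-155-5p and -0.55 (SE 0.29, adjusted p = 0.308) for miR-146a-5p by edgeR. Of the miRNAs induced by hypoxia or p53, miR-34a-5p had a log2 fold change of 0.68 (SE 0.42, adjusted p = 0.361), and 0 of 2 tested members passed, over all tested or adjusted over the list alone.

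No tested marker of mature blood lineages passed the threshold. Of 4 tested myeloid miRNAs 0 passed, over all tested or adjusted over the list alone (median 0.17, camera adjusted p = 0.617), and miR-223-3p, the main myeloid miRNA, stood at 8939 ± 1411 CPM in db/m and 8603 ± 2834 CPM in db/db (SD, n = 4 each; log2 fold change -0.06, SE 0.23, turning positive under scaling by library totals, 0.04, or without the 5 most abundant miRNAs in the library size). Of 7 tested lymphoid miRNAs 0 passed in either way. Their median of -0.08 and mean of 0.15 had opposite signs, with an upward camera direction (adjusted p = 0.808) that turned downward without a filter (median -0.28), and the median turned positive under scaling by library totals (0.04) and without db/m replicate 3 (0.042) or db/db replicate 4 (0.13). miR-150-5p, abundant in mature lymphocytes, had a log2 fold change of -0.63 (SE 0.27, adjusted p = 0.183 by edgeR, and 0.0461 without db/m replicate 3), miR-181c-5p 1.00 and miR-181a-5p, the most abundant member, -0.08 (SE 0.32), turning to 0.04 under scaling by library totals. The erythroid list had 1 tested member, miR-486a-5p, at 2701 ± 551 CPM in db/m and 2714 ± 2109 CPM in db/db (SD, n = 4 each), with a log2 fold change of -0.01 (SE 0.43), which turned positive under scaling by library totals (0.10) or without the 5 most abundant miRNAs in the library size. It did not pass over all tested or adjusted over the list alone.

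Few markers of cells outside the blood system were tested, 2 of 16 stromal and endothelial ones and 2 of 25 of other tissues. Of the stromal and endothelial markers 0 passed, over all tested or adjusted over the list alone, and miR-152-3p had 860 ± 367 CPM in db/m and 657 ± 121 CPM in db/db (SD, n = 4 each), and miR-199a-3p 224 ± 120 and 379 ± 334 CPM. Of the markers of other tissues 0 passed in either way. miR-203-3p, known from epithelium, stood at 1473 ± 428 CPM in db/m and 1934 ± 338 CPM in db/db, and miR-122-5p, known from liver, at 613 ± 565 and 467 ± 171 CPM (SD, n = 4 each). miR-1a-3p, which marks skeletal and heart muscle, was kept out of the test by the filter. It had 1135 and 839 CPM in db/db replicates 3 and 4 and between 19.2 and 242 CPM in the other 6 libraries, with a log2 fold change of 1.81 (SE 0.72, adjusted p = 0.188) by edgeR without the filter. From the imprinted Dlk1-Dio3 cluster of chromosome 12 only miR-127-3p was tested, with a log2 fold change of -1.18 (SE 0.44, adjusted p = 0.136 by edgeR, and 0.0328 without db/m replicate 3). miR-101a-3p was the tested miRNA of the Lepr neighbourhood. Its hairpin lies on chromosome 4 from 101346945 to 101347027, in an exon of the long noncoding RNA E130102H24Rik and 370377 bp from Lepr (101717404 to 101815352). Each of these last 2 was the lone tested member of its list, so adjusted over the list alone it passed. miR-451a and miR-210-3p were not analysed here.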

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

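Of the tests in this part, the list test without miR-126a and the test of miRNAs near Lepr were chosen after the results they measure had been seen. Among 88 groups of 4 libraries, 7 held a library far from the other 3, where chance picks out about 1 in 20, or 4.4.

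miR-126a-3p stood at 6724 CPM in db/m replicate 4, against 10080 to 10240 in the other 3 db/m libraries. miR-191-5p stood at 39520 CPM in db/m replicate 3, against 33930 to 34230. In db/m replicate 2, with 13273 counts, 180 miRNAs had a count, against 190 in each of the others, and db/db replicate 1 had 189 against 190. miR-30a-5p stood at 1224 CPM in db/db replicate 2, against 618 to 714, and miR-101a-3p at 2079 CPM in the same library, against 1281 to 1405. miR-203-3p stood at 1432 CPM in db/db replicate 3, against 2040 to 2143.

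The count of 7 miRNAs past the threshold was reached by 1 of the 35 splits of the 8 libraries, the real one. The highest count of any other split was 1. This argues against libraries that happened to be alike as the source of the count, but 1 of 35 is the smallest share these splits can give. No title number occurs in both genotypes, so likeness of libraries that share a number could also peak at the real split and was not excluded. Within a genotype, deviations of libraries with the same number had a mean correlation of -0.368, against -0.278 with different numbers. Such likeness thus did not show, but these means come without a spread. For the lists the splits could not decide, because 35 of 35 splits gave 0 or more lists, with 0 in the real split and 2 at the highest elsewhere.

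The rise of miR-126a-3p and miR-126a-5p was set against 3 technical explanations. Without the shallowest library, db/m replicate 2, the smaller log2 fold change was 1.43 (edgeR adjusted p = 0.00729 for both, and at most 0.0328 over all alternatives), and after removal of the trend of log2 fold change on hairpin GC content (-0.123 per 10 percentage points, SE 0.0543) it was 1.35, which argue against low depth and GC content as the whole cause. Stromal or endothelial cells that escaped the lineage-negative, Sca1 and cKit gate may carry miR-126a. Without the filter 3 stromal markers had a median log2 fold change of 0.56, that of miR-199a-3p with an SE of 0.59, too wide to decide. They were miR-143-3p at 86.3 CPM in db/m and 181 in db/db, miR-199a-3p at 224 and 379, and miR-152-3p at 860 and 657. Endothelial cells were not tested separately, so they stay open too. A larger share of stem and progenitor cells rich in miR-126 is a further candidate explanation, and the other 12 members of that list gave a camera p of 0.109 (0.457 with an estimated correlation), so it stays open, as does a change inside the cells with genotype, which was not tested. The muscle marker miR-1a-3p stood at 1135 and 839 CPM in db/db replicates 3 and 4, and at 19.2 to 242 in the other 6 libraries. Among the db/db libraries miR-126a-3p was lowest in replicate 3 (14100 CPM) and highest in replicate 4 (32680 CPM), so it did not follow this marker.

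The fall of miR-423-5p, miR-320-3p and miR-148a-3p was tested against depth and GC content. Without db/m replicate 2 the log2 fold change nearest to 0 among the 3 was -1.11 (highest edgeR adjusted p = 0.0355), and after removal of the GC trend it was -0.92, each still below 0 by more than 2 SE. Both values argue against these sources as the whole cause. An effect of genotype stays open as a hypothesis, and the calls of miR-320-3p and miR-148a-3p, whose log2 fold changes stayed between -1.15 and -0.97 and between -1.64 and -1.24 with 1 library left out, were lost without 3 single libraries, with adjusted p of 0.0726 and 0.0924 without db/m replicate 1, 0.0702 and 0.0611 without db/m replicate 4, and 0.0533 and 0.101 without db/db replicate 1.

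miR-101a-3p, encoded 370377 bp from Lepr, had a log2 fold change of 1.08 at an unadjusted p of 0.00827 that did not pass adjustment. Exchange of reads with its near copy miR-101b-3p could move single counts, yet the summed counts of both had a log2 fold change of 0.95 (SE 0.33), which argues against it. The chromosome 4 interval inherited with the db mutation may also act, and the 4 other miRNAs encoded within 20 Mb of Lepr (miR-30c-5p, miR-30e-3p, miR-30e-5p and miR-872-5p) had a median log2 fold change of 0.28 without the filter, where miR-101a-3p was at 1.02, from -0.20 to 0.63, between miR-30c-5p (SE 0.23, and 0.03 with the filter) and miR-872-5p (SE 0.41). miR-30e-3p (-0.20) and miR-30e-5p (0.63) are strands of the same hairpin, so the 4 are not separate loci. miR-30c-5p is also encoded on chromosome 1 and so does not measure the interval alone, and without it the median is that of miR-872-5p, 0.62, so these few members leave the interval open. Linked sequence and the mutation itself go together with genotype in this design.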

How the results depend on the processing

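Among the alternatives in this part, the authors' test was chosen after the data were examined. The count of 7 stayed at 7 with RLE size factors, library totals, or library size without the 5 most abundant miRNAs, and was 5 without a filter. The filter at 10 CPM removed no miRNA and so equals no filter. The count was 16 with DESeq2 (28 miRNAs had no adjusted p), 12 with the likelihood ratio test, 12 with limma-voom, 13 at an adjusted p of 0.1, 26 with the title number as a random block, whose correlation was negative (-0.288), 21 with libraries of 1 title number summed, and 10 with the authors' test. Against 4 higher and 3 lower, these were 8 and 8 with DESeq2, 5 and 7 with the likelihood ratio test, 4 and 8 with limma-voom, 12 and 14 with the random block, 15 and 6 with libraries summed, 4 and 6 with the authors' test, and 2 and 3 without a filter. With 1 library left out the count ran from 3 to 16 (3 without db/m replicate 1, db/m replicate 4 or db/db replicate 1, 16 without db/m replicate 3). miR-126a-3p, miR-126a-5p and miR-423-5p passed in all 21 settings, miR-320-3p in 18, miR-148a-3p in 17, miR-30a-5p in 14 and miR-196b-5p in 13. The highest adjusted p of these 7 was 0.442, for miR-148a-3p with libraries summed.

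The number after the hyphen of the title did not pair the samples: deviations of libraries of different genotype with the same number had a mean correlation of 0.0111 (-0.351 to 0.314). With it as a replicate block 11 miRNAs passed, 5 of them among the 7, and 0 lists. miR-30a-5p and miR-196b-5p then had adjusted p of 0.0617 and 0.0632.

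The count of lists stayed at 0 except for 1 by fry and, with 1 library left out, 0 to 1. The let-7 share difference was -3.78 percentage points, and -4.64 to -3.20 with 1 library left out. That of the 5 most abundant miRNAs, which did not pass adjustment, was -3.82 and ran from -4.27 to -3.34. The difference in mean total counts, -234.8, ran from -11330 to 10190.

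Scaling by library totals raised the median log2 fold change by 0.11 and no filter lowered it by 0.08, so miRNAs near 0 changed sign. Their log2 fold changes lay between -0.08 and 0.08. With library totals, miR-16-5p was at 0.032, let-7f-5p at 0.070, miR-486a-5p at 0.096, miR-181a-5p at 0.035 and miR-223-3p at 0.043. Without the 5 most abundant miRNAs in the library size, miR-16-5p was at 0.0090, let-7f-5p at 0.047, miR-486a-5p at 0.059 and miR-223-3p at 0.022. Without a filter, miR-125a-5p was at -0.054, miR-30d-5p at -0.012 and the lymphoid list at a median of -0.28, its camera direction turned. With libraries summed, miR-16-5p was at 0.086, let-7f-5p at 0.21 and miR-486a-5p at 0.10. limma-voom gave 0.018 for let-7f-5p, the likelihood ratio test 0.00094 for miR-486a-5p, and the authors' test -0.054 for miR-125a-5p and -0.016 for miR-30d-5p. The block gave -0.11 for miR-125a-5p, 0.17 for miR-486a-5p and 0.23 for miR-181a-5p. With 1 library left out the ranges were -0.17 to 0.044 for let-7f-5p, -0.14 to 0.16 for miR-125a-5p, -0.72 to 0.22 for miR-486a-5p, -0.44 to 0.13 for miR-181a-5p, -0.058 to 0.12 for miR-30d-5p and -0.17 to 0.16 for the median of the miR-17 clusters. Medians of lists also turned sign where the direction of camera did not: NF-kB and inflammation to -0.048 without db/db replicate 1, diabetes to -0.027, -0.0088 and -0.017 without db/m replicate 2, db/m replicate 4 or db/db replicate 2, lymphoid to 0.035 with library totals, 0.042 without db/m replicate 3 and 0.13 without db/db replicate 4, and the miR-17 clusters to 0.0066 with RLE, 0.095 with library totals and 0.27 with the block. None of these passed the threshold, and apart from the shifts in scaling the cause was not tested. Over all named miRNAs and lists, 864 values kept their direction (for a list that of its test, not of its median) and side of the threshold, 76 newly passed, 22 no longer passed and 43 turned direction. Depth limits miRNAs near 229 CPM, the worth of 3 counts in db/m replicate 2.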

Other observations

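Where both strands of a hairpin were counted, the signs of their log2 fold changes matched in 14 of 27 hairpins, strands near 0 included. The comparison of strands was chosen after the data were examined. These 27 are the hairpins with both strands in the table, and the signs are those without the filter. Some strands lay near 0, such as miR-425-3p (0.0011) and miR-140-3p (-0.0057), where the sign is not settled. The count therefore does not tell whether strands of a hairpin move together. For miR-126a both strands rose, and the log2 ratio of the 5p over the 3p strand was -2.17 ± 0.28 in db/m and -1.97 ± 0.06 in db/db (SD, n = 4 each; exact permutation p = 0.171). For miR-423 the 5p strand fell, and miR-423-3p, with a log2 fold change of -0.05 (SE 0.27), stood at 1610 ± 175 CPM in db/m and 1564 ± 511 CPM in db/db. The log2 ratio of its strands was 2.30 ± 0.24 in db/m and 1.00 ± 0.27 in db/db (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible). Only miR-423 had an exact permutation p under 0.05. Benjamini-Hochberg adjustment over the 27 hairpins made that p 0.514, but with 4 libraries against 4 a single hairpin could not pass it whatever its difference, so the adjusted p decides nothing. The unadjusted p does not decide either, since 1 such value among 27 hairpins is close to what chance gives. Being the smallest possible, that p also does not measure the size of the gap. The log2 ratio differed by -1.30 between the genotypes, against SDs of 0.24 and 0.27 within them. miR-423-5p had already passed the threshold in these same libraries, so the ratio is no separate support. The miR-25 hairpin, inside the Mcm7 gene, showed -2.92 ± 0.44 in db/m and -3.65 ± 0.29 in db/db (SD, n = 4 each; exact permutation p = 0.0571).

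miR-503-5p of the miR-15/16 family, too low for the test at 1 to 17 counts per library, had 82.2 ± 39.6 CPM in db/m and 199 ± 113 CPM in db/db (SD, n = 4 each). The groups overlapped, at 38.3 to 134 CPM in db/m and 66.2 to 330 CPM in db/db. Without the filter edgeR gave a log2 fold change of 1.12 (SE 0.59, adjusted p = 0.291), which did not pass. On a principal component analysis of log2 CPM the first component held 40% of the variance and set db/m replicate 2, the shallowest library, apart at -8.92, with the other 7 between -2.39 and 4.23. Across 130 tested miRNAs with a known GC content of the matching side of the hairpin, log2 fold change and GC content had a Spearman correlation of -0.166 (permutation p = 0.06), taken across miRNAs that are not independent replicates.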
